A study of Homo sapiens with 16 samples.

How the data were processed

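Total RNA of monocytes from healthy volunteers was hybridised to Affymetrix expression arrays, 1 array per sample. Monocytes were purified from blood with RosetteSep antibodies, which remove other cells, per the series design text, and RNA was extracted with Trizol and made into biotin-labelled cRNA, per the labels' protocols. The values were deposited by the authors as 1 table of 8793 probe sets by 16 arrays with no missing value. RMA was used to make them, per the submitters' processing notes; its version, settings and annotation are not given in the sources used here. The deposited values were taken as log2: RMA writes log2 values, the numbers were signed, and their spacing fitted 32-bit log2 levels, but no source names the base.

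The deposited log2 values had been centred for each probe set. Tested on the table, the median of the 7 pre-feeding and 3 parenteral arrays was 0 in 8793 of 8793 probe sets, within 1.5e-06. The 3 lipid arrays held symmetric pairs around 0 in 490 probe sets (5.57%) and did not share that median. In the 3 enteral arrays 425 probe sets had 2 arrays at exactly 0 and 26 had all 3 at 0. What the enteral and lipid references were could not be recovered, so absolute levels were lost and every contrast with those arrays holds an unknown offset. Rounding of 32-bit numbers left the original level's range visible for 89.4% of probe sets, and 872 genes could be placed at a log2 level of 8 or more.

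Of the probe sets, 47 were controls, 7840 had 1 gene symbol in the platform annotation, 388 had several and 518 non-control probe sets had none. Symbols were looked up by gene ID in the RefSeq gene table, which held 7838 of the 7840, and 0 symbols changed. Probe sets with several symbols or none were not named. Sex-linked genes were left out (22 probe sets), leaving 7827 probe sets. Of the genes, 122 had several probe sets, which were averaged, giving 7700 genes. A set of 28 genes with common deletions or haplotypes was tested and counted but not named. Comparisons were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 16 arrays and 4 groups, two-sided, with 12 residual and 3.27 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values for genes in the text come from this model unless another is named.

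The groups, comparisons, tests, 34 gene lists, alternatives and rule for named genes were fixed before the data were examined. The centring forced 3 departures, made before any model was fitted: no filter on dim genes, a mean over a gene's probe sets in place of the brightest one, and eBayes without a trend, since all rested on mean levels that the centring removed. Two-sided exact permutation tests of list means and control probe sets (scipy 1.17.1) used the 10 arrays of the shared reference. Lists of 4 to 46 measured genes, 609 genes in all, covered markers of other blood cells and monocyte subsets and functions from metabolism to inflammation. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance. Named genes were up to 10 per direction with the largest differences past the threshold in primary comparisons (3 in secondary ones), filled to 5 (3) by rank of p where fewer passed, and up to 4 members of each list by p. Members named outside this rule are marked as such.

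A total of 6 subjects gave a pre-feeding and a fed array, as their subject numbers in the labels show. The deviations of the paired arrays from their group means correlated at 0.299, 0.548, 0.275, 0.47, 0.271 and 0.399 in subjects A, E, F, H, I and J, so the numbers pair the arrays. The subject was left out of the main model, as fixed beforehand, and entered as a random block (consensus correlation 0.392, statmod 1.5.0) or a fixed block (3 residual degrees of freedom) as alternatives. The arrays were treated as independent samples, although these 6 subjects gave a pre-feeding and a fed array each. The main model and the permutation tests ignore that pairing. Their p-values measure the spread between arrays, not between independent people. No scan date or batch was given in the sources used here.

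Other alternatives fixed beforehand were the compared groups alone, every probe set, quantile normalization, centring of each array on its median, the variance trend first planned, array weights and leaving out each array in turn. Those chosen after seeing the data were a filter on a log2 level of 8, the 3-prime minus 5-prime control difference or the platelet list mean as a covariate over 10 arrays, and leaving out the 3 pre-feeding arrays with the highest control difference. The code was tested on simulated data with 200 of 7700 genes changed in the parenteral against pre-feeding comparison. It recovered 45.5%, 86.5% and 98.5% of them at log2 changes of 0.5, 1 and 2, with 8, 6 and 22 false calls, and made 0 calls with no change. This tests the code and not the false calls on the real arrays, where other splits of this comparison gave up to 379 genes. Figures were drawn with matplotlib 3.10.9 from values computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.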

Results

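Gene expression was measured in blood monocytes, the circulating phagocytes that give rise to macrophages, from healthy volunteers before feeding and at 72 h. The series set enteral feeding, given into the gut, against parenteral feeding, given into a vein,. The 16 arrays came from 10 subjects, lettered A to J here. Of these, 7 arrays were taken before feeding, 3 after enteral feeding, 3 after parenteral feeding and 3 after parenteral feeding with lipid. A pre-feeding array was present for 6 of the fed subjects, 2 in each fed group, so comparisons between routes were comparisons between different people. Each array carried 8793 probe sets, from which 7700 genes were tested. The number of arrays per group limited the precision of every difference below. The SD of the values on one array lay between 0.224 and 0.386 log2 units.

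The deposited values were log2 levels minus a reference for each probe set, and that reference was not the same for all groups. The median of the 7 pre-feeding and 3 parenteral arrays was 0 in 8793 of 8793 probe sets, so these 10 arrays shared a reference. The enteral arrays held 1329 to 1546 values of exactly 0 each, against 2 to 13 in every other array, and the lipid arrays were centred on another reference again. A comparison of parenteral with pre-feeding arrays therefore rested on a common scale. Every comparison with enteral or lipid arrays carried an unknown offset for each gene, which no p-value below covers, and is given as a difference between deposited values.

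RNA quality also differed between the groups on the common scale. The arrays carry probe sets at the 3-prime and 5-prime ends of the GAPDH and actin transcripts, and a larger 3-prime minus 5-prime difference accompanies less intact RNA. This difference, averaged over both transcripts, was -0.803 ± 0.0814 log2 units (SD, n = 3) in parenteral arrays and 0.911 ± 1.29 (SD, n = 7) in pre-feeding arrays. The groups differed by -1.71 (two-sided exact permutation test, p = 0.0167, the smallest this test can give here). Pre-feeding arrays of subjects A, E and I stood highest, at 2.37, 2.09 and 2.08. The first principal component of the 10 arrays, with 36.9% of the variance, placed the same 3 arrays at one end, with scores of 21.6, 19.7 and 18.5. Its scores in parenteral and pre-feeding arrays did not differ past the threshold (exact permutation p = 0.0833).

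**Figure D1:**
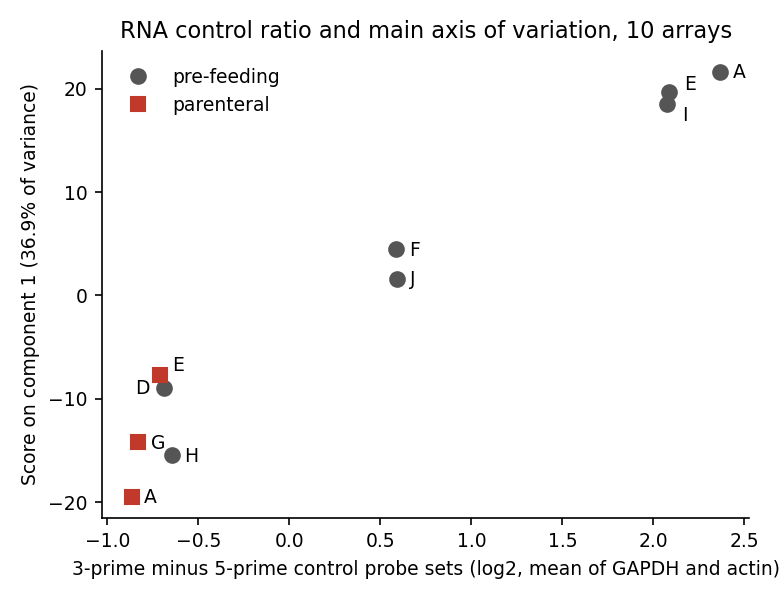
Score on the first principal component (vertical axis) against the 3-prime minus 5-prime control difference in log2 units (horizontal axis) for the 7 pre-feeding (circles) and 3 parenteral (squares) arrays, each point 1 array with its subject letter. Pre-feeding arrays of subjects A, E and I lie apart at 2.37, 2.09 and 2.08, and the 3 parenteral arrays lie between -0.866 and -0.711.

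The first comparison asked what 72 h of parenteral feeding changed. SLC25A20, the mitochondrial carrier that brings fatty acids bound to carnitine into the matrix for oxidation, fell by 1.04 on the log2 scale (SE 0.12, limma adjusted p = 0.00211). Its mean was 0.16 ± 0.19 (SD, n = 7) before feeding and -0.87 ± 0.20 (SD, n = 3) after parenteral feeding, and every parenteral array lay below every pre-feeding array. It was the only gene of 7700 past the threshold, while 930 genes had an unadjusted p under 0.05 against 385 expected by chance. Without the 3 pre-feeding arrays of highest 3-prime minus 5-prime difference 376 genes did, and with that difference as a covariate 306. Both lie under 385, so the excess was not seen in those settings. With quantile normalization 9 genes passed, all lower. Among genes at a log2 level of 8 or more 0 passed, but SLC25A20 had no value under that filter, so its call was not tested there. Other genes of fatty acid use stood on the same side without passing. ETFB, a subunit of the flavoprotein that takes electrons from acyl-CoA dehydrogenases, differed by -0.57 (SE 0.12, adjusted p = 0.232). ACAA2, the thiolase of the last step of mitochondrial beta-oxidation, differed by -0.96 (SE 0.20, adjusted p = 0.232), and PLIN2, a coat protein of lipid droplets, by -0.94 (SE 0.21, adjusted p = 0.232).

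Other genes named by rank did not pass either. PON2, a paraoxonase with antioxidant activity, differed by -0.99 (adjusted p = 0.0515). KLF11 and KLF10, transcription factors induced by TGF-beta, differed by -1.11 and -1.84 (adjusted p = 0.232 for both); without the parenteral array of subject A, KLF10 stood at -1.20. On the higher side stood ANAPC5, of the anaphase-promoting complex, at 0.66, and GRB2, an adaptor of receptor tyrosine kinases, at 0.69. TMOD3, which caps actin filaments, stood at 1.08, ZMAT3, a p53-induced RNA-binding protein, at 0.69, and BATF, an AP-1 family transcription factor, at 0.47 (adjusted p = 0.232 for each).

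Pairing by subject enlarged the count. With the subject as a random block, 21 genes passed, 8 higher and 13 lower, among them SLC25A20, PON2, ETFB, ACAA2, PLIN2, KLF10 and KLF11. FKBP5, a glucocorticoid-induced chaperone, named after its value was seen, was among those higher, at 1.44. With the subject as a fixed block, which rests on the pairs of subjects A and E alone, 875 genes passed, 378 higher and 497 lower. In those pairs the 3-prime minus 5-prime difference also moved, by -3.23 in subject A and -2.80 in subject E. When that difference entered the unpaired model as a covariate, SLC25A20 differed by -1.01 (SE 0.17) with an adjusted p of 0.714, and no gene passed in limma. In that model 306 genes had an unadjusted p under 0.05, against 385 expected by chance. SLC25A20 also lost its call with the platelet list as a covariate, at -0.91 (adjusted p = 0.327). Over the 10 alternatives for SLC25A20, the adjusted p ran from 0.000803 to 0.714, and the call held in the other 8 and without any single array.

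**Figure D2:**
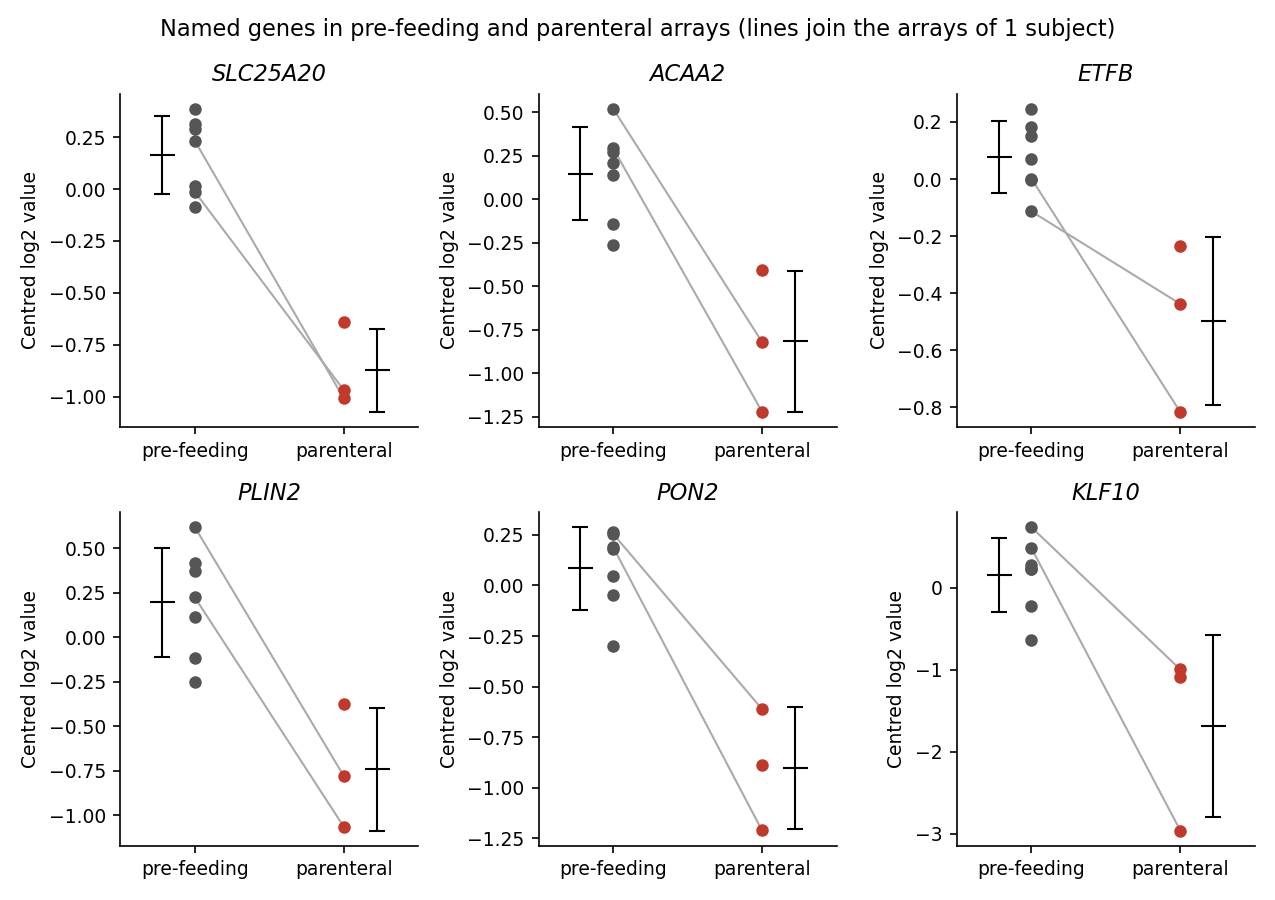
Centred log2 value (vertical axis) of 6 named genes in the 7 pre-feeding and 3 parenteral arrays, each point 1 array, with lines joining the arrays of 1 subject and bars giving the mean ± SD. SLC25A20 was the gene past the threshold, with means of 0.16 and -0.87; the other 5 panels show genes that did not pass without pairing.

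The list of fatty acid oxidation genes and their PPAR regulators, fixed beforehand, lay lower after parenteral feeding, by a mean of -0.29 over its 27 measured members. Of these, 20 had negative and 7 positive differences; 1 fell over all genes tested and 10 fell adjusted over the list alone. Beside SLC25A20, ETFB, ACAA2 and PLIN2, the members past the list's own threshold, named after their values were seen, included ETFDH at -0.65, which passes electrons from beta-oxidation to ubiquinone, and ACADVL at -0.65, the dehydrogenase of very long chains. CPT1A, the rate-limiting step of mitochondrial fatty acid entry, stood at -0.32, and PDK4, a kinase that holds back pyruvate oxidation, at -0.82. HADHB, the beta subunit of the trifunctional protein, and ECI2, an enoyl-CoA isomerase, completed the 10, at -0.44 and -0.68. Of the regulators, also named after their values were seen, PPARA stood at -0.05, PPARG at 0.05 and PPARD at -0.04. The list passed limma's camera test (adjusted p = 6.17e-06), but not with an estimated correlation between genes (adjusted p = 0.158 with an estimated correlation); fry, the self-contained test, gave an adjusted p of 0.00514 for this list and of 0.256 to 0.478 for the 10 other lists past camera, none of which passed it. Its mean per array was -0.222 ± 0.104 (SD, n = 3) after and 0.0723 ± 0.0634 (SD, n = 7) before feeding (exact permutation p = 0.0167, adjusted over 34 lists p = 0.113). The B cell, dendritic cell, glycolysis and chemotaxis and adhesion lists shared this p, the smallest that the test can give. In the parenteral arrays the 3-prime minus 5-prime control difference was lower by 1.71, as above, and the platelet marker list higher by a mean of 0.74. With these as covariates the list mean stood at -0.23 and -0.29, and the camera call held with each. Among genes bright enough to reach a log2 level of 8, which left 4 of the 27 members, the mean was -0.05 and the call was lost.

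**Figure D3:**
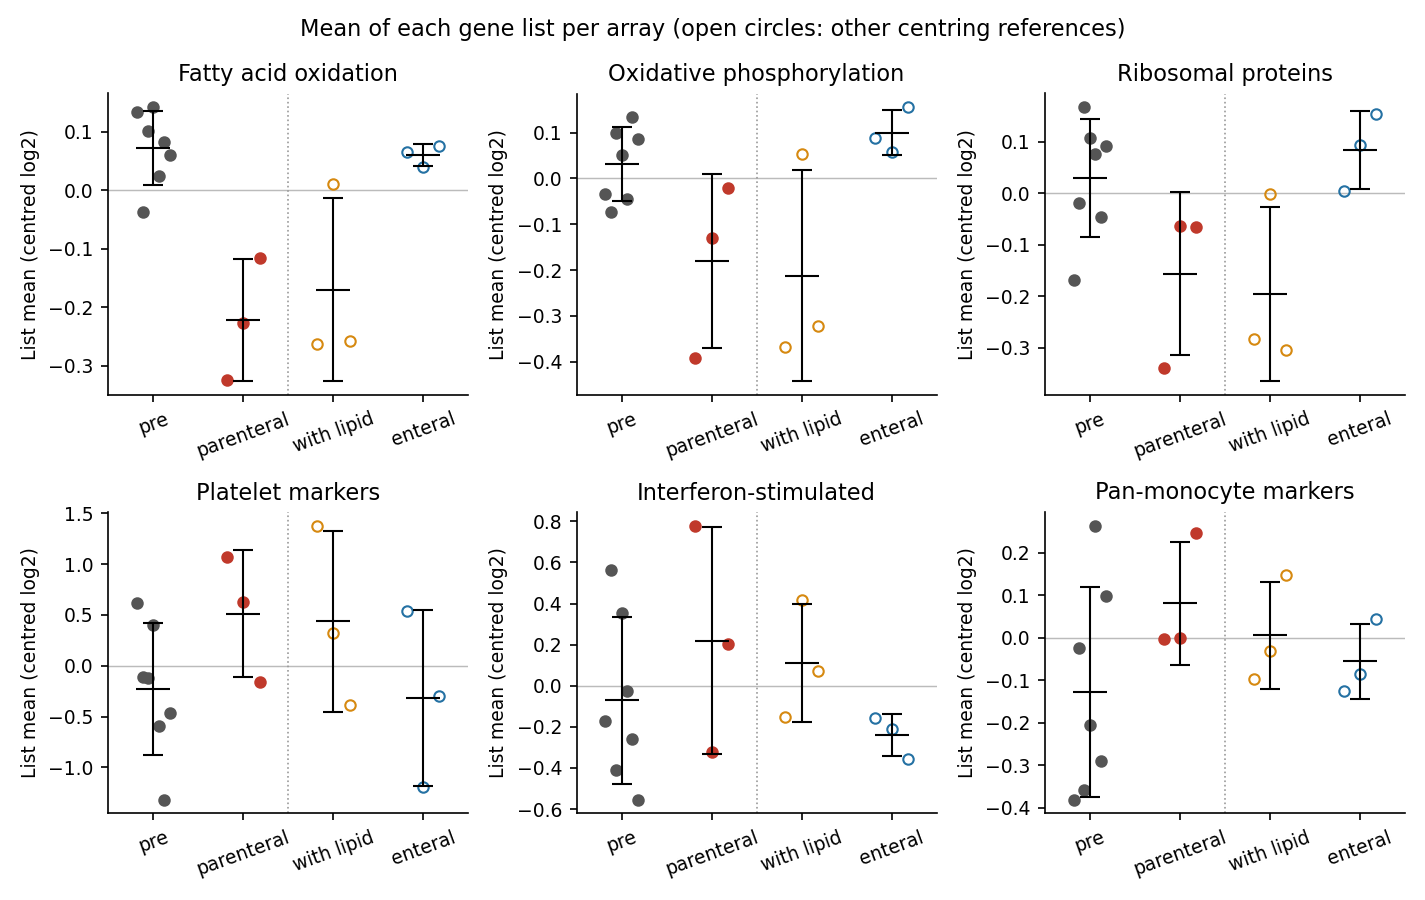
Mean centred log2 value of 6 gene lists (vertical axes) per array, by group, each point 1 array and bars the mean ± SD of the group; open circles mark enteral and lipid arrays, whose references differ from the common one. In the first panel the parenteral arrays average -0.222 against 0.0723 before feeding, and in the platelet panel the 3 parenteral arrays spread by 0.625 (SD).

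Genes of the respiratory chain and the ribosome lay slightly lower in the parenteral arrays. Of 46 oxidative phosphorylation genes, 41 had negative differences with a list mean of -0.21; none passed over all genes and 1, the complex I subunit NDUFB8 at -0.41, fell adjusted over the list alone. The complex IV subunits COX5A, COX7C and COX6C differed by -0.42, -0.59 and -0.40 without passing, and COX7C and COX6C by -0.39 and -0.24 without the parenteral array of subject A. Of 41 cytosolic ribosomal protein genes, 35 had negative differences with a list mean of -0.19, and no member passed over all genes or adjusted over the list alone. Both lists passed camera (adjusted p = 1.55e-07 and 3.11e-07), and neither passed with an estimated correlation (adjusted p = 0.589 for both with an estimated correlation). Without the parenteral array of subject A the means were -0.11 and -0.09, with both camera calls kept. The proteasome list, with 20 of 25 members negative and a mean of -0.13, passed camera as well (adjusted p = 0.0201; adjusted p = 0.633 with an estimated correlation), but lost its call without the parenteral array of subject A (-0.01) or the pre-feeding arrays of subjects E (-0.11) or F (-0.11), and stood at -0.22 without the parenteral array of subject G. The lower 3-prime minus 5-prime difference and the higher platelet markers of the parenteral arrays accompanied these lists too, and with the platelet list as a covariate the oxidative phosphorylation mean was -0.13.

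Of the lists of other blood cell markers, those of platelets, B cells and natural killer cells passed camera, while T cell, plasma cell, granulocyte, erythroid and dendritic cell lists did not. All 18 platelet markers had positive differences, with a mean of 0.74; TUBB1, the platelet tubulin, stood at 2.14 and ITGB3, the platelet fibrinogen receptor subunit, at 1.65, neither passing over all genes nor adjusted over the list alone. The platelet list passed camera (adjusted p = 3.88e-05; adjusted p = 0.633 with an estimated correlation), while its mean per array did not differ past the threshold (exact permutation p = 0.15). Without the parenteral array of subject A the platelet difference was 0.46, with the camera call kept, and ITGB3 stood at 1.06. All 12 B cell markers had negative differences, with a mean of -0.39 (camera adjusted p = 0.00129; adjusted p = 0.589 with an estimated correlation); 1 of them, the B cell adaptor BLNK at -1.17, fell adjusted over the list alone. The natural killer list averaged -0.37 (camera adjusted p = 0.0457; adjusted p = 0.635 with an estimated correlation), a call that 10 of the 16 single-array omissions ended, as did the platelet covariate (-0.21). Its mean was -0.20 without the parenteral array of subject A, -0.22 without the pre-feeding array of subject D and -0.57 without the parenteral array of subject G.

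The classical and pan-monocyte lists passed camera and the nonclassical list, at a mean of 0.04 (exact permutation p = 0.85), did not. The mean was 0.26 for the classical list (camera adjusted p = 0.00599; adjusted p = 0.589 with an estimated correlation) and 0.21 for the pan-monocyte list (camera adjusted p = 0.0457; adjusted p = 0.633 with an estimated correlation). No member passed over all genes or adjusted over either list alone. CD14, the lipopolysaccharide co-receptor, differed by 0.66, the scavenger receptor CD163 by -0.41 and the calprotectin subunit S100A9 by 0.53, while SPI1, the myeloid master regulator, differed by 0.89. With the 3-prime minus 5-prime difference as a covariate, CD14 stood at -0.01, SPI1 at -0.31 and the pan-monocyte list at -0.07. Without the 3 pre-feeding arrays of least intact RNA, the pan-monocyte and interferon calls were lost, at means of 0.05 and 0.13. The pan-monocyte call was lost in 12 of the 16 single-array omissions, with a mean of 0.13 without the parenteral array of subject G, and the classical call without the parenteral array of subject E (0.26). The interferon-stimulated list averaged 0.29 (camera adjusted p = 0.00159; adjusted p = 0.633 with an estimated correlation), with the antiviral enzymes OAS2 at 0.65 and OAS1 at 0.58, but averaged 0.01 without the parenteral array of subject A, where OAS2 stood at 0.29, 0.56 without that of subject E and -0.04 with the covariate. The immediate early list averaged -0.33 (camera adjusted p = 0.0163; adjusted p = 0.633 with an estimated correlation), and 3 of its 24 members, KLF10, JUND at -0.57 and KLF4 at -0.58, fell adjusted over the list alone; its call was lost without the parenteral array of subject E (-0.28), and its mean was -0.18 with the 3-prime minus 5-prime covariate. With the platelet list as a covariate, the classical, interferon, immediate early and proteasome calls were lost, at means of 0.22, 0.11, -0.14 and -0.05. With the subject as a fixed block, the B cell, classical, immediate early and proteasome calls were lost, at -0.30, 0.17, -0.31 and -0.20, and as a random block the natural killer call. The fixed block also moved the pan-monocyte and interferon means to 0.37 and 0.52, with both calls kept.

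Parenteral feeding with lipid was set against pre-feeding across 2 references. No gene passed in limma, and 1040 genes had an unadjusted p under 0.05. The lower deposited values nearest the threshold belonged to MCCC1, a carboxylase of leucine breakdown, at -0.72 (SE 0.13), PON2 at -0.87 (SE 0.16), the centrosomal protein OFD1 at -0.87, GIT2, a regulator of ARF signalling, at -0.67, and the metalloprotease ADAM28 at -1.08 (adjusted p = 0.174 for each). On the higher side stood the keratin KRT9 at 0.53, GIT1 at 0.60 (0.37 without the lipid array of subject H), EML3 at 0.42, CORO1C at 0.48 and the adhesion molecule ICAM1 at 1.20 (adjusted p from 0.174 to 0.248). The fatty acid oxidation list averaged -0.24, with 8 members lower adjusted over the list alone and none over all genes. SLC25A20 stood at -0.52, ETFDH at -0.73 and PLIN2 at -0.76. Oxidative phosphorylation averaged -0.24, ribosomal proteins -0.23 and the proteasome -0.19, and platelet markers averaged 0.67. No member of these 4 lists passed over all genes, and 1, 0, 2 and 0 passed adjusted over the list alone. All 5 lists passed camera and none passed with an estimated correlation (adjusted p of 0.524 for the fatty acid list and 0.660 for the other lists with an estimated correlation). The platelet call was lost without the lipid array of subject C, where the mean was 0.19, and the proteasome call likewise, at -0.08. The platelet mean was 1.08 without the lipid array of subject H, and the proteasome mean -0.31 without that of subject F. The platelet call was also lost with the subject as a fixed block, where the mean was 0.06; that block moved the oxidative phosphorylation and proteasome means to -0.14 and -0.11 with both calls kept, and without the lipid array of subject F the oxidative phosphorylation mean was -0.38. With the subject as a fixed block 8 genes passed, and without the lipid array of subject F 116 did.

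Enteral feeding, also across references, showed no gene past the threshold against pre-feeding in limma. Only 80 genes had an unadjusted p under 0.05, fewer than the 343 to 423 seen in 20 simulated sets of unchanged independent arrays, and than the 251 to 294 in 20 sets with arrays paired by subject. Real genes vary together, which widens the range of such counts under no change, and the narrow simulated ranges show no such widening. They therefore cannot tell whether 80 is unusually low. The higher deposited values nearest the threshold were those of LGMN, a lysosomal protease, at 0.53 (SE 0.11), the transcription factor BCL11A at 0.56, BLNK at 1.07, the tropomyosin TPM2 at 0.86 (0.52 without the enteral array of subject J) and the cytotoxic protease GZMB at 1.15. The lower ones were those of the macrophage chitinase CHIT1 at -0.39, GRB7 at -0.26, CKAP4 at -0.71, XPNPEP1 at -0.48 and RDH16 at -0.28, with an adjusted p of 1 for each of the 10. The interferon-stimulated list averaged -0.17, with 21 of 24 members negative and none past either threshold (camera adjusted p = 0.0095; adjusted p = 0.861 with an estimated correlation). That call was lost with the subject as a random or a fixed block, the latter with a mean of 0.12, and without enteral arrays of subjects I (-0.18) or J (-0.11) or pre-feeding arrays of subjects D (-0.06) or F (-0.10). Without the 3 pre-feeding arrays of least intact RNA the mean was -0.33, with the call kept.

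The mean of all fed arrays was set against pre-feeding to look for a difference shared by the routes. No gene passed in limma, with 505 genes at an unadjusted p under 0.05. SLC25A20 stood lowest in rank at -0.49 (SE 0.09, adjusted p = 0.333), followed by PON2 at -0.52, PLAAT3, a phospholipase, at -0.58, KLF11 at -0.67 and NDUFB8 at -0.26 (adjusted p = 0.713 for each). KRT9 at 0.30, ICAM1 at 0.74, ZMAT3 at 0.36, the cytokine signal transducer STAT3 at 0.67 and RAD9A at 0.22 stood highest in rank. The fatty acid oxidation list averaged -0.18, with 22 of 27 members negative, 8 lower adjusted over the list alone and none over all genes (camera adjusted p = 2.8e-06; adjusted p = 0.131 with an estimated correlation). Platelet markers averaged 0.44, and B cell, oxidative phosphorylation, ribosomal and proteasome lists averaged -0.19, -0.13, -0.12 and -0.09; these passed camera and stood at an adjusted p of 0.689 with an estimated correlation, with no member past over all genes or adjusted over the list alone. The B cell call was lost without the enteral array of subject B (-0.16), the pre-feeding arrays of subjects D (-0.19) or F (-0.11) or the lipid array of subject F (-0.16), and the proteasome call without the parenteral array of subject A (-0.06) or with the subject as a fixed block (-0.08); without the lipid array of subject C its mean was -0.06. The platelet mean was 0.26 without the pre-feeding array of subject I, 0.28 without the lipid array of subject C and 0.27 with the fixed block, with its call kept. With the subject as a random block 1 gene passed, and as a fixed block 212.

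The series title names the contrast of enteral with parenteral feeding. Between deposited values of enteral arrays and those of both parenteral groups, 185 genes passed, 130 higher and 55 lower in enteral arrays, and 1453 genes had an unadjusted p under 0.05. Among genes past the threshold, the largest positive differences were those of GZMB at 2.28 (SE 0.36), BLNK at 2.18 (SE 0.29), KLF10 at 1.64, SERPINF1, which encodes pigment epithelium-derived factor, at 1.60, and ADAM28 at 1.41. They were followed by the dendritic cell lectin CLEC10A at 1.32, the mismatch repair protein PMS1 at 1.27, OFD1 at 1.25, the splicing factor SF3A2 at 1.25 and PON2 at 1.23. The largest negative differences among genes past the threshold were those of TUBB1 at -2.81 (SE 0.63), the kinase HIPK3 at -2.37, TAGLN2 at -2.13, DAZAP2 at -1.81 and TLR8, the endosomal receptor of single-stranded RNA, at -1.60. GFI1B, a transcription factor of platelet precursors, stood at -1.45, TMOD3 at -1.36, FCAR, the IgA receptor, at -1.36, TLR4, the lipopolysaccharide receptor, at -1.30 and EXOC5 at -1.29. The adjusted p of these 20 genes lay between 0.00445 and 0.0477. The offset between references is part of each difference, and without the enteral array of subject J 6 genes remained past the threshold in number, against 382 without the lipid array of subject F. With the subject as a fixed block 6 genes passed.

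The same comparison moved 12 of the 34 lists past camera, and none passed with an estimated correlation (adjusted p from 0.548 to 0.647 with an estimated correlation). In the fatty acid oxidation list, 20 of 27 members were higher in enteral arrays with a mean of 0.26; 5 passed over all genes, SLC25A20 at 0.85, ETFB at 0.67, PLIN2 at 0.92, ACAA2 at 0.87 and, named after its value was seen, ECI2 at 0.99, and 8 adjusted over the list alone. Oxidative phosphorylation genes averaged 0.30, with 43 of 46 positive, 1 past over all genes (NDUFB8 at 0.54) and 13 adjusted over the list alone. Ribosomal protein genes averaged 0.26, with 39 of 41 positive, 2 past over all genes (RPL37 at 0.43 and RPL22 at 0.46) and 10 adjusted over the list alone. Heat shock genes averaged 0.24, with the chaperones HSPH1 at 0.89 and HSPD1 at 0.67 past over all genes and 3 adjusted over the list alone. Proteasome genes averaged 0.19, with 1 past over all genes, PSMD14 at 0.79, and 2 adjusted over the list alone. B cell markers averaged 0.44 (1 past over all genes and 3 adjusted over the list alone) and dendritic cell markers 0.42 (2 and 4), with FLT3, a growth factor receptor of dendritic cell precursors, at 0.98. Lower in enteral arrays were the lists of platelet markers at -0.80 (1 and 1), erythroid markers at -0.63, interferon-stimulated genes at -0.41, classical monocyte markers at -0.30 and granulocyte markers at -0.18, the last 4 with no member past either threshold. CD163, the haemoglobin scavenger receptor, was higher at 0.80. Leaving out the enteral array of subject I ended the platelet (-0.36), erythroid (-0.52), dendritic (0.35) and classical monocyte (-0.20) calls, and that of subject J the erythroid (-0.54), proteasome (0.14) and heat shock (0.20) calls. Leaving out the parenteral array of subject A ended the erythroid (-0.51), proteasome (0.13) and heat shock (0.20) calls, and that of subject E the erythroid call (-0.52). Leaving out lipid arrays ended the erythroid (-0.41) and proteasome (0.13) calls for subject C, the dendritic call (0.40) for F and the heat shock call (0.21) for H; the granulocyte call ended in 13 of 16 omissions, with means of -0.10 without lipid C and -0.11 without enteral I, and its mean was -0.27 without enteral B. With calls kept, the interferon mean was -0.27 without the parenteral array of subject A and the platelet mean -1.22 without the enteral array of subject B. With the subject as a fixed block the granulocyte (-0.05) and classical monocyte (-0.10) calls ended too, and the platelet, interferon and B cell means moved to -0.19, -0.17 and 0.78 with their calls kept. As a random block the granulocyte call ended as well, and so it did without the 3 pre-feeding arrays of least intact RNA (-0.18).

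Against each parenteral group alone, fewer genes passed. Enteral minus parenteral gave 20 genes, 14 higher and 6 lower, led by GZMB at 2.30 (SE 0.42), BLNK at 2.23, SERPINF1 at 1.46, DAZAP2 at -1.81, TLR8 at -1.68 and TMOD3 at -1.51 (adjusted p from 0.012 to 0.0492). SLC25A20 stood at 1.11 (SE 0.14, adjusted p = 0.00723) and ETFB at 0.76. Enteral minus parenteral with lipid gave 11 genes, all higher, with GZMB at 2.26, BLNK at 2.13 and SERPINF1 at 1.74 (adjusted p from 0.0206 to 0.0453), while DAZAP2 at -1.81, CKAP4 at -1.25 and XPNPEP1 at -0.99 did not pass (adjusted p = 0.0572 for each). Of 34 lists, 11 and 12 passed camera in these comparisons and none with an estimated correlation, and the offset between references enters both. The first count of genes was 0 without the parenteral array of subject A and 70 with the subject as a random block. The second was 0 without the lipid array of subject H or the enteral array of subjects I or J, and 171 without the lipid array of subject F. With the subject as a fixed block these counts were 23 and 0.

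Within parenteral feeding, arrays with and without lipid did not differ past the threshold in any of the 7700 genes in limma, and 31 genes had an unadjusted p under 0.05. SLC25A20 stood highest in rank, at 0.52 (SE 0.14, adjusted p = 1), with ASMT at 0.27 and the immediate early transcription factor EGR3 at 0.55 (0.34 without the lipid array of subject C). HIRA, a histone chaperone, stood at -0.92, the importin KPNA4 at -0.43 (-0.65 without the lipid array of subject F) and HOXD11 at -0.27 (-0.16 without the parenteral array of subject A). The immediate early list averaged 0.30, with 20 of 24 members higher with lipid and none past either threshold (camera adjusted p = 4.64e-06; adjusted p = 0.966 with an estimated correlation), a call lost without the lipid array of subject C, at 0.19, and with the subject as a fixed block, at 0.27; without the lipid array of subject H the mean was 0.47. The 2 groups were centred on different references, and with the subject as a fixed block 69 genes passed, 10 higher and 59 lower with lipid. That block sets the lipid pairs of subjects F and H against the parenteral pairs of subjects A and E. In the pairs of A and E the 3-prime minus 5-prime difference moved by -3.23 and -2.80, so RNA quality may enter the 69.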

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

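Tests of the splits, of inherited variation and of lower RNA quality in all pre-feeding arrays were chosen after their values or the results were seen, and the covariate tests of platelets and of RNA quality in parenteral arrays, the own-reference test and the test of subjects A and E were chosen before their values were computed. Results were picked out here where deposited values of fed groups differed by a direct test. Without pairing, that test compares fed arrays of different people, and the unknown offset between references enters each count. A difference was found for 20 genes and 11 lists between enteral and parenteral arrays, 11 genes and 12 lists between enteral and lipid arrays, and 1 list, immediate early genes, between lipid and parenteral arrays. With the subject as a fixed block, 23, 0 and 69 genes passed in these comparisons, in that order. The lists are those past camera at its preset correlation, and with an estimated correlation 0 of them passed in each comparison. A search for a single pre-feeding array apart from the other 6 in 45 items, the 34 list means, the SD of the array and 10 named genes, found 0, but it cannot see 3 arrays that stand apart together, as those of subjects A, E and I did in the control difference, which was not among the items.

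The lower fatty acid oxidation and oxidative phosphorylation lists in parenteral arrays were weighed against platelet RNA and RNA quality. For fatty acid oxidation, the difference of -0.294 (SE 0.0523) was -0.287 (SE 0.0647) with the platelet list as a covariate and -0.231 (SE 0.0594) with the 3-prime minus 5-prime control difference, more than 2 SE below 0 in both, which argues against either trend as the whole cause. Lower RNA quality in parenteral arrays is also excluded for oxidative phosphorylation, since their control difference was lower by the value -1.71, the direction of more intact RNA. For that list, -0.212 (SE 0.0817) became -0.13 (SE 0.0814) with the platelet covariate and -0.147 (SE 0.104) with the RNA covariate. Both fall within 2 SE of 0. That was written beforehand as the sign of a cause for platelet RNA, and afterwards for lower RNA quality in pre-feeding arrays. The covariate slopes were -0.1105 (SE 0.05596) for the platelet list and 0.0381 (SE 0.0372) for the RNA covariate. Neither was over 2 SE, a condition added afterwards, which the platelet slope narrowly missed. Platelet RNA and RNA quality therefore cannot be told apart from feeding here. An effect of parenteral feeding on fatty acid oxidation genes may be proposed as a hypothesis, found and tested on the same 10 arrays; fasting state before feeding was not tested.

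The enteral arrays differed from the mean of both parenteral groups in 185 genes, from parenteral arrays alone in 20, and from pre-feeding arrays in 0 in limma, with 80 genes at an unadjusted p under 0.05. Centring parenteral arrays on their own median cut the genes at an unadjusted p under 0.05 from 930 to 6, below the 80 of the enteral arrays, but centring a group on itself lowers this number by construction, so the test leaves open whether the enteral reference could account for the pattern. A reference from people with other inherited variation was not decided either: in 14 genes with common deletions or haplotypes, the within-subject difference in enteral subjects was 0.818 times that in parenteral subjects (95% interval over resampled genes 0.597 to 1.11), but 1.27 times (0.927 to 1.73) once each group was set against its difference over all genes, where an added offset would enlarge it. Either ratio rests on 2 subjects per group, and the parenteral pairs also differ in RNA quality. A true difference between routes, the reference and the different people stay open and cannot be told apart. Marker lists of platelets, erythroid cells, B cells and dendritic cells also passed camera in the comparison with both parenteral groups, as given above. No test of the share of other cells is given here, and one of the monocyte share was dropped after its value had been seen.

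Pairing by subject as a fixed block raised the parenteral count from 1 to 875 genes, all 875 of the same sign as without the block. Of the 874 named genes, 94.4% differed opposite to their slope on the 3-prime minus 5-prime control difference among the 5 other pre-feeding arrays, against 68.2% of the other genes (r across genes -0.702; genes are not independent replicates). The pre-feeding arrays of subjects A and E were among the 3 with the least intact RNA, so lower RNA quality there is a candidate explanation for most of that count. For fatty acid oxidation, the paired mean was -0.39 against the -0.12 that those slopes give, though 8 of its 9 genes past the threshold went opposite to their slope. For oxidative phosphorylation it was -0.29 against -0.22, with 9 of 9. Of the other lists past camera, the platelet (0.61 against 0.89), pan-monocyte (0.37 against 0.44) and classical (0.17 against 0.25) means had the sign that the slopes give. So did the interferon (0.52 against 0.62), immediate early (-0.31 against -0.64) and proteasome (-0.20 against -0.07) means. The ribosomal (-0.20 against 0.06), natural killer (-0.53 against 0.42) and B cell (-0.30 against 0.06) means had the opposite sign. Among the 5 arrays behind all these slopes, that of subject I lay far from the others in control difference (2.08 against -0.688 to 0.593). It was also lowest in the platelet list (-1.32 against -0.59 to 0.40). Slopes without it were not computed, so their signs may depend on that 1 array. A feeding effect in subjects A and E was not separable from RNA quality.

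Other splits of the compared arrays, fitted as 2 groups alone so that real counts can differ from those above, were counted for each comparison. For parenteral against pre-feeding, 4 of 100 splits gave at least the real 1 gene, a share under 0.05, yet the highest other split gave 379. Those splits ignore the pairing by subject, so that share cannot exclude chance. Among the 24 that part 2 pairs, as the real one does, 2 gave at least 1 gene, a share over 0.05, and the other 22 gave 0. Chance is therefore not excluded. For enteral against both parenteral groups, 2 of 84 splits gave at least the real 247 genes, the highest other giving 251. The enteral arrays have a reference of their own, which every other split mixes with those of the parenteral arrays. An offset alone could therefore raise the real count, so this share decides nothing about feeding. The same holds for enteral against parenteral arrays below. Where the real count was 0, 100 of 100 splits match it by construction, which decides nothing about chance; the highest others were 147 for enteral, 136 for lipid and 1405 for all fed arrays against pre-feeding. Splits that call many times the real count point to a structure of the samples, which was not traced further. For parenteral against pre-feeding, the split of 379 genes is among the 24 above. Those 24 include the split that sets apart the pre-feeding arrays of subjects A, E and I, of least intact RNA. Whether that split gave the 379 was not examined. With 3 arrays against 3 only 10 splits exist, too few for a share under 0.05; the real and highest other counts were 57 and 1 for enteral against parenteral (1 split as large), 0 and 3 for enteral against lipid and 0 and 1 for lipid against parenteral (10 splits as large in both).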

How the results depend on the processing

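Covariates, the level filter and the omission of 3 pre-feeding arrays were chosen after seeing the data; the other settings were fixed beforehand. The filters on dim genes by mean level, and taking the brightest probe set, could not be run, since the centring removed mean levels, and signal over background is unknown for the same reason. The level filter keeps fewer genes, and the fixed block leaves 3 residual degrees of freedom. Why counts fell or rose under any setting was not tested. The number of genes changed, with its value above each time, became as follows. For parenteral against pre-feeding it was 21 with the replicate block as a random and 875 as a fixed effect, 9 with quantile normalization, and 0 with the RNA covariate or with the platelet covariate. It was also 0 at a level of 8 or more, a filter under which SLC25A20 had no value. With the fixed replicate block it was 1 for enteral, 8 for lipid and 212 for all fed against pre-feeding (1 for all fed with the random block), 6 for enteral against both parenteral groups, 0 for enteral against lipid and 69 for lipid against parenteral. For enteral against both parenteral groups it was 103 with the compared groups alone, 674 with array weights and 62 at a level of 8 or more. For enteral against parenteral it was 70 with the random block, 57 with the compared groups alone, 116 with quantile normalization, 293 with array weights, 4 at a level of 8 or more and 31 without the 3 pre-feeding arrays of least intact RNA. For enteral against lipid it was 0 with the compared groups alone, 36 with quantile normalization, 76 with array weights and 26 without those 3 arrays.

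Leaving out single arrays gave 1 to 2 genes for parenteral against pre-feeding (2 without lipid C, pre-feeding D, parenteral E or enteral J), 0 to 116 for lipid against pre-feeding (116 without lipid F), 6 to 382 for enteral against both, 0 to 75 for enteral against parenteral and 0 to 171 for enteral against lipid. For enteral and all fed against pre-feeding and lipid against parenteral it stayed at 0. Enteral against both moved over 1.5 times without enteral J (6), B (27) or I (47), parenteral A (47), lipid H (69) or F (382) and pre-feeding F (106), J (118) or H (290). Enteral against parenteral did so without parenteral A (0), E (7) or G (51), enteral I (1), J (2) or B (8), lipid H (6) and pre-feeding E (6), F (7), J (10), I (53) or H (75). Enteral against lipid did so without enteral I or J or lipid H (0), lipid C (35) or F (171) and pre-feeding E or J (5), F (7), D or I (18) and H (40).

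Values that changed direction follow, first for parenteral against pre-feeding. With the RNA covariate, CSF3R was -0.3503, CD14 -0.01439, SPI1 -0.307, IFITM3 -0.01305, OASL -0.04774 and the pan-monocyte list -0.07357. Without the 3 pre-feeding arrays CSF3R was -0.009173. With the fixed replicate block SPIB was 0.04438, JCHAIN 0.4278 and S100A12 -0.001176, and without single arrays JCHAIN ran from -1.177 (parenteral E left out, direction kept) to 0.5453 (parenteral G left out, direction changed). With the fixed block the interferon list was 0.1242 for enteral against pre-feeding and 0.04446 for enteral against lipid, and the platelet list 0.08446 for enteral against lipid. At a level of 8 or more, where 4 members remain, the direction of the fatty acid oxidation test turned, with means of 0.007927, -0.01031 and 0.02617 for enteral against both, parenteral and lipid arrays. The list mean itself changed sign only against parenteral arrays. Over all lists past camera and all comparisons, 294 results kept direction and call under alternatives other than omissions, 177 lost the call and 7 reversed; under omissions 832 kept it and 112 lost it. For named genes 1926 kept direction and side of the threshold, 153 passed newly, 95 lost the call and 9 reversed; under omissions 3508, 84, 311 and 1 did.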

Other observations

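For parenteral against pre-feeding arrays, on the shared reference, the dendritic cell marker list averaged -0.26 and passed no adjusted test, with 9 of 13 members negative (camera adjusted p = 0.0788). The mean per array was -0.133 ± 0.0789 (SD, n = 3) after and 0.124 ± 0.116 (SD, n = 7) before feeding (two-sided exact permutation p = 0.0167, adjusted over 34 lists p = 0.113). FLT3, a growth factor receptor of dendritic cell precursors, differed by -0.75 and CD1C, a lipid-presenting molecule of conventional dendritic cells, by -0.75, and no member passed over all genes or adjusted over the list alone. The lists of glycolysis, higher by 0.109, and of chemotaxis and adhesion, higher by 0.147, had the same permutation p and adjusted p. So did the B cell and fatty acid oxidation lists.

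Glucocorticoid-induced genes went both ways. FKBP5, a chaperone of the glucocorticoid receptor, differed by 1.21, the matrix protein THBS1, also abundant in platelets, by 1.51 (0.86 without the parenteral array of subject E), and the formyl peptide receptor FPR1 by 0.80, while the decoy receptor IL1R2 stood at -0.52 and TXNIP, a glucose-responsive inhibitor of thioredoxin, at -0.29 (adjusted p from 0.271 to 0.319). None of the 19 members passed over all genes; 3 rose and 2 fell adjusted over the list alone. The list did not pass camera (adjusted p = 0.627), and FKBP5 stood at 0.48 with the RNA covariate. CRY1, a repressor of the circadian clock, stood at -0.67 and SREBF1, a regulator of lipid synthesis, at 0.41, each past the threshold adjusted over its own list alone and not over all genes (adjusted p = 0.296 for both). These genes were picked out after their values were seen.

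Differences from pre-feeding in the parenteral and lipid arrays correlated across genes (r = 0.864, covariance 0.0596). Both use the same 7 pre-feeding arrays, and 20 simulated sets of unchanged independent arrays gave r = 0.3 and a covariance of 0.0114, against 0.168 and 0.00533 with arrays paired by subject at a correlation of 0.392. With the pre-feeding arrays split between the comparisons in 35 ways, r had a median of 0.64 (0.318 to 0.744) and the covariance a median of 0.0495. Genes are not independent replicates, the lipid arrays have another reference, and pre-feeding arrays of less intact RNA enter both sides.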
